A study of Mus musculus with 6 samples.

How the data were processed

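Poly(A) RNA of the piriform cortex of Gad2-Cre mice was measured in 6 libraries, 3 that the labels assign to Cre-dependent caspase 3 virus and 3 to Cre-dependent GFP virus. Per the labels' protocols, RNA was isolated with TRIzol and libraries were made with a kit that labels the second cDNA strand. HISAT2, featureCounts and DESeq2, and the builds mm10 and GRCm38, are named in the submitters' processing notes, with no roles, versions or parameters. The strand setting of the counting is not given in the sources used here.

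The deposited count table held whole-number read counts for 53715 genes with Ensembl identifiers, gene names, coordinates and lengths, per the file headers. Of its identifiers, 53620 were found in GENCODE M21 (GRCm38), 52056 of them with identical start and end and 52030 with the identical name. The deposited FPKM table held FPKM values per the file headers. In each library its values equalled the count divided by gene length and by a constant for the library, up to a common factor, and the constant, 95.6% to 105.6% of the total count, equalled the DESeq2 size factor times the geometric mean of the library totals. FPKM values were used only in alternatives. Groups and replicate numbers were taken from the sample titles.

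Genes were tested on the deposited counts with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM factors, glmQLFit and glmQLFTest, intercept and group, all 6 libraries), and 16721 genes passed the filter. Benjamini-Hochberg adjusted p under 0.05 counted as changed. CPM values are counts scaled to library totals times TMM factors, and the SE of a log2 fold change is its absolute value divided by the square root of F. For 34 gene lists (676 symbols, 672 in the table, 597 tested), camera in limma 3.58.1 was run on log2 CPM (prior count 2) with a preset correlation of 0.01, with an estimated correlation, and beside fry. The 33 lists with at least 5 tested members were tested, and 22 were placed (12 higher, 10 lower). With an estimated correlation none was placed (lowest adjusted p = 0.184), and fry, which asks whether a list moves one way on balance, called 9. These were the interferon, antigen presentation, cytokine, T and NK cell, complement, cell death and immediate early lists and both microglia lists. Fry did not call the GABAergic, interneuron, channel, glutamate receptor or vesicle lists (fry adjusted p = 0.0514 to 0.313). Comparison with 0 or few counts used a floor of 3 counts over the group or an exact 95% interval, which cover counting error only.

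Tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule names Gad2, Gad1, Slc32a1, Pvalb, Sst, Vip, Gfap and Fos. It adds up to 4 changed members per list with the smallest adjusted p, or where none changed the 1 tested member with the highest mean CPM. It further adds the 8 largest rises and 8 largest falls among changed genes with a mean of at least 1 CPM and groups that do not overlap, leaving out predicted genes. Some genes under this rule are not reported here. Drd2, Adora2a, Tac1, Penk, Cd8b1, Nr4a1, Jun, Arc, Npas4, Bax, Bbc3, Pax5, Hcar2 and Prdm12 were named after their values were seen. Alternatives were DESeq2 size factors, upper-quartile factors or library totals, DESeq2 1.42.0, limma-voom, limma on log2(FPKM + 0.1) and log2(FPKM + 1), robust edgeR, other filters and thresholds, the sample number as a block, and each library left out. The DESeq2 alternative, which gave the single-gene and total DESeq2 results, covered all 31638 genes with a count. DESeq2 counts per gene list came from a separate run on the 16721 filtered genes. After seeing the data, a fit without Caspase3 replicate 1 and GFP replicate 3, and camera under other scalings, were added.

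The tests were tried on simulated counts for the 16721 genes of this comparison, drawn from the real means, totals and dispersions. In them 200 genes were changed, and a separate list of 20 genes was raised 1.5-fold. Recovery was counted among the 200. edgeR recovered 20.9% of genes changed 1.5-fold, 62.7% of those changed 2-fold and 93.9% of those changed 4-fold, and 8.33% of its calls were unchanged genes. Camera found the list of 20 raised genes with either correlation (adjusted p = 6.57e-13 and 0.0396). The simulated genes were drawn independently, whereas the estimated correlation within the real lists reached 0.82. This trial therefore does not show how camera performs, with either correlation, on lists whose genes vary together. Replicates of a group differed by more than sampling noise, with a mean chi-square per gene of 12.6 to 32.8. Of 119 genes examined by name, 11 have an exon that overlaps an exon of another tested gene in GENCODE M21: Cxcl10, Tap1, Gjd2, Jun, Grn, Hexa, Gbp4, Rnf213, Eif2ak2, Crispld1 and Pax5. Their counts could hold reads of the neighbour. Figures were drawn with Matplotlib 3.10.9.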

Results

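Poly(A) RNA from the piriform cortex, the olfactory cortex at the base of the forebrain, was sequenced in bulk from Gad2-Cre mice. These mice make Cre recombinase in cells that express Gad2, an enzyme that synthesises the inhibitory transmitter GABA. The piriform cortex of 1 side had received an adeno-associated virus with either Cre-dependent caspase 3, a protease that executes apoptosis, or Cre-dependent GFP as the control. The Caspase3 group and the GFP group held 3 libraries each. Total counts lay between 20424581 and 24227361 in the Caspase3 libraries and between 22101015 and 26268377 in the GFP libraries, and 3 counts in a library corresponded to 0.118 to 0.142 CPM (counts scaled to library size). The labels used here give neither the hemisphere sampled nor the interval after injection, and transgene reads were not counted. They do not say that the libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may be technical in part.

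The comparison addresses what accompanies the delivery of Cre-dependent caspase 3 to Gad2-expressing cells in a model studied for features of epilepsy, and cell numbers were not measured. The targeted gene was examined first. Gad2 (ENSMUSG00000026787, chromosome 2, 22622205 to 22693874, GRCm38) was 3.04-fold lower in the Caspase3 group, at 34.4 ± 6.67 CPM (SD, n = 3) against 104.7 ± 12.8 CPM (SD, n = 3). Its log2 fold change was -1.60 ± 0.15 (SE), with an adjusted p of 0.00371 in edgeR's quasi-likelihood test. The highest Caspase3 library, at 38.5 CPM, lay below the lowest GFP library, at 92.4 CPM. Gad1, which encodes the other GABA-synthesising enzyme, stood at 125.0 ± 68.5 against 312.9 ± 73.6 CPM, and Slc32a1, the vesicular GABA transporter, at 13.9 ± 6.20 against 37.1 ± 18.9 CPM. Neither passed the test over all genes (log2 fold changes -1.32 and -1.42, adjusted p = 0.130 and 0.163). Without Caspase3 replicate 2, Gad1 passed, with a log2 fold change of -1.86 and an adjusted p of 0.013, as it did with the replicate block (0.00902) and with no filter on low counts (2.47e-09), and its adjusted p ranged up to 0.427 over all alternatives. Slc32a1 passed with no filter only (1.53e-08, against up to 0.468). The edgeR fit with no filter called 913 genes against 274. It also passed Drd2, a striatal gene high in GFP replicate 3 alone (adjusted p = 1.27e-09, against 0.247 with the filter). Passing with no filter therefore does not show a difference beyond the spread between libraries.

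**Figure D1:**
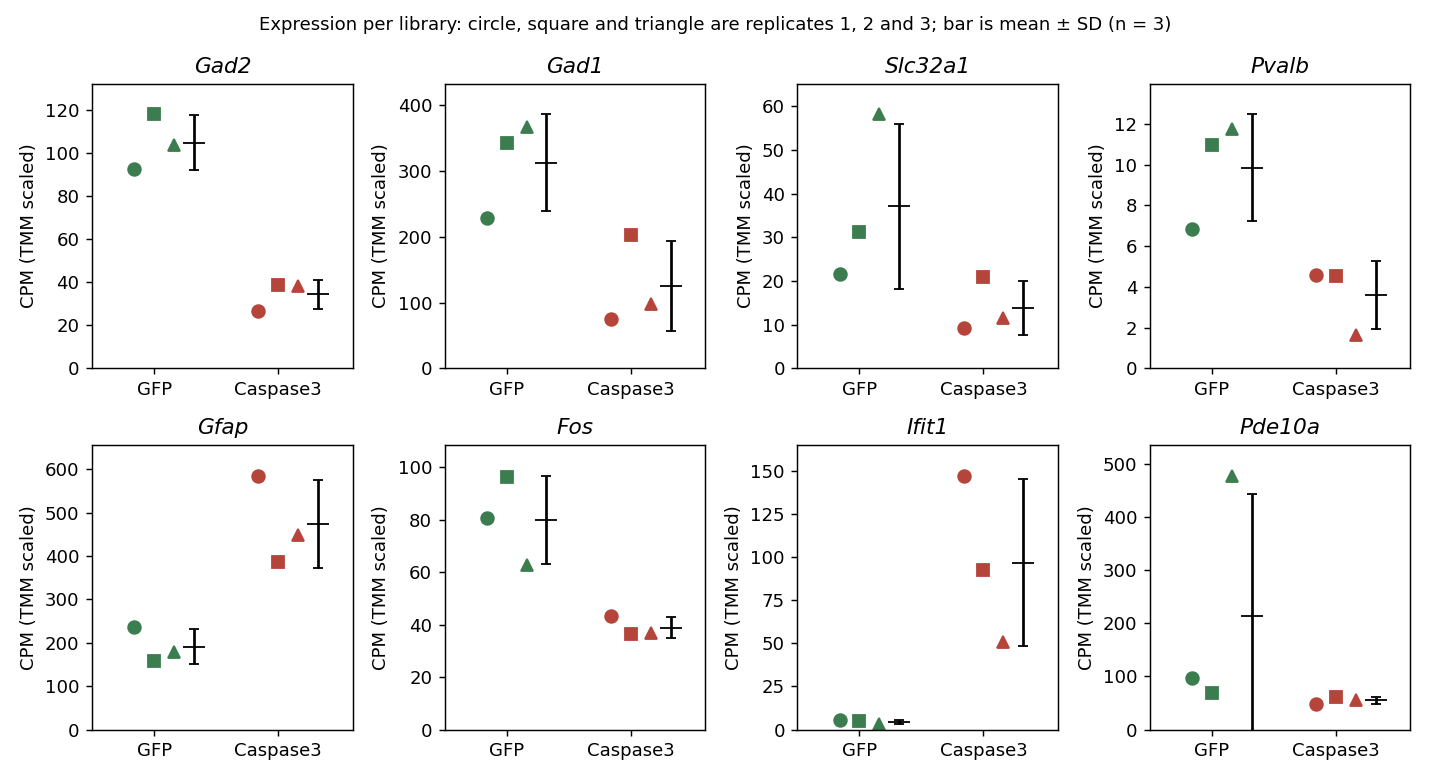
CPM, scaled by TMM factors, of 8 genes in each library, with GFP in green and Caspase3 in red. Circles, squares and triangles are replicates 1, 2 and 3, whose numbers are not said to pair libraries across the groups. The black bars give mean ± SD (n = 3). The Gad2 values of the Caspase3 libraries all lie below those of the GFP libraries, and Pde10a stands at 477.8 CPM in GFP replicate 3 alone. The SD bar of Pde10a extends below 0 and is drawn to 0.

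Of the 19 GABAergic neuron markers, Gad2 fell, 1 other member rose and 17 did not pass. The median log2 fold change of the list was -0.72 (-1.14 without Caspase3 replicate 2), and 16 of 19 members had negative values. DESeq2 called 5 lower and 1 higher, limma-voom 1 and 1, and edgeR with no filter on low counts 11 and 1. With p adjusted over the list alone, 11 members were lower and 2 higher. The set test camera placed the list lower (adjusted p = 6.9e-07), while the adjusted p was 0.246 with an estimated correlation between genes. Among 24 tested interneuron subtype genes, Kcns3, a potassium channel subunit, fell 3.25-fold (log2 fold change -1.70 ± 0.33, adjusted p = 0.0397) and 23 did not pass. In this list 4 were lower when adjusted over the list alone, 3 with DESeq2, 1 with limma-voom and 6 with no filter. Pvalb, the calcium-binding protein of fast-spiking interneurons, was at 3.60 ± 1.68 against 9.85 ± 2.62 CPM (log2 fold change -1.46 ± 0.36, adjusted p = 0.112). The peptides Sst and Vip, which mark other interneuron classes, had log2 fold changes of -0.46 ± 0.48 and -0.78 ± 0.38 (adjusted p = 0.792 and 0.523). Pvalb passed with DESeq2 and with no filter (adjusted p = 0.000478 and 1.35e-06, and up to 0.354 elsewhere), Vip with no filter alone (0.00916, and up to 0.899), and Sst in no alternative. The list was placed lower by camera (adjusted p = 2.09e-06; 0.301 with an estimated correlation). Kcns3 missed the threshold when any library other than Caspase3 2 was left out (adjusted p = 0.0735 to 0.167). The GABAergic list held no rise when any library other than Caspase3 1 was left out, and held 3 falls without Caspase3 2 and 2 without GFP 1.

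Striatal transcripts were highest in 1 GFP library. Drd2 and Adora2a, receptors of striatal projection neurons, stood at 23.7 and 42.4 CPM in GFP replicate 3, against 1.03 and 3.12 CPM in GFP replicate 1 and 0.515 and 1.66 CPM in GFP replicate 2. Pde10a, a phosphodiesterase of the same neurons, stood at 477.8, 96.3 and 68.9 CPM in GFP replicates 3, 1 and 2 and at 54.9 ± 6.84 CPM (SD, n = 3) in the Caspase3 group. Striatal projection neurons are themselves GABAergic, and Tac1 and Penk belong both to this list and to the interneuron list. None of the 17 tested striatal markers passed with edgeR, DESeq2 or limma-voom, 10 had an unadjusted p under 0.05, and 10 were lower adjusted over the list alone. The DESeq2 alternative gave Drd2 and Adora2a no adjusted p. With no filter on low counts, edgeR passed members of this list, among them Drd2 and Adora2a (adjusted p = 1.27e-09 and 1.45e-08). The median log2 fold change of the striatal list was -1.58 over all libraries (camera adjusted p = 8.87e-06, and 0.403 with an estimated correlation). It was -0.42 without GFP replicate 3. Leaving out GFP replicate 3 therefore does not address a striatal difference that remains between the other libraries. Without that library, Gad2 still fell, with a log2 fold change of -1.62 (adjusted p = 0.0169), and the median of the GABAergic list was -0.61. Gad2 was highest, at 118.0 CPM, in GFP replicate 2.

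Across all genes, rises outnumbered falls. Of 16721 genes tested, 274 passed an adjusted p of 0.05, of which 255 rose and 19 fell in the Caspase3 group. The change was at least 2-fold for 222 of the rises and 9 of the falls, and at least 4-fold for 120 and 1. The median log2 fold change was 1.87 among the rises and -0.84 among the falls. CPM values of the groups did not overlap for any of the 274 genes, nor for 15.2% of all tested genes, where chance gives 10%. The counts depended on single libraries. Without GFP replicate 2, 15 genes were higher and 2 lower, all 17 among the 274, and without GFP replicate 3 the counts were 131 and 13. Falls numbered 33 without Caspase3 replicate 1 and 7 without Caspase3 replicate 3. Without both Caspase3 replicate 1, the farthest from its group, and GFP replicate 3, 260 genes were higher and 77 lower, with 205 of the 274 among them. All 274 genes kept their direction in each of these fits. Groups that do not overlap all but require this, so it is no test of stability. On the first principal component of the 1000 most variable genes, with 59.4% of the variance, the Caspase3 libraries lay between 17.8 and 33.4 and the GFP libraries between -30.2 and -14.5.

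**Figure D2:**
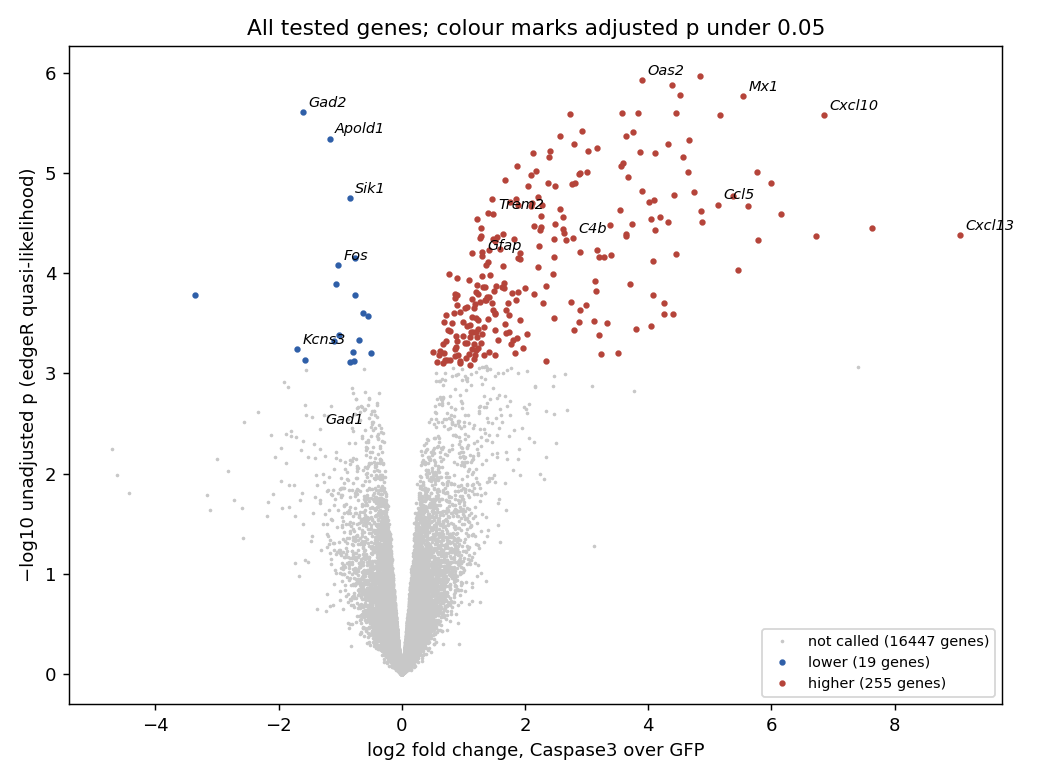
Fitted log2 fold change (Caspase3 over GFP) against -log10 of the unadjusted p for the 16721 tested genes. Red points are the 255 genes that rose and blue points the 19 that fell at an adjusted p under 0.05, and Cxcl13, which had no count in the GFP libraries, is drawn at its fitted value, which is no estimate of its fold.

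Interferon-stimulated genes rose in the Caspase3 group without exception among those listed. All 35 list members passed, with a median log2 fold change of 3.03. Ifit1, which binds viral RNA, rose from 4.59 ± 1.23 to 96.7 ± 48.3 CPM (log2 fold change 4.39 ± 0.39, adjusted p = 0.00371). The antiviral GTPase Mx1 and its homologue Mx2, annotated as a polymorphic pseudogene, rose 46.7-fold and 14.3-fold, and Oas2, which senses double-stranded RNA, rose 14.9-fold (log2 fold changes 5.54 ± 0.51, 3.83 ± 0.37 and 3.90 ± 0.34). Among 22 antigen presentation genes, 13 rose and none fell. The class I genes H2-Q7, H2-Q4 and H2-T23 rose 11.9-fold, 6.64-fold and 4.29-fold, and Tap1, a peptide transporter, rose 5.19-fold. Reads of the H2 genes may be divided among near-identical copies. Camera placed both lists higher (adjusted p = 4.63e-53 and 4.49e-21), with an adjusted p of 0.184 for each with an estimated correlation. The counts adjusted over the list alone were 35 and 17 higher, with DESeq2 35 and 14, and with limma-voom 33 and 10. Without GFP replicate 2, 6 interferon-stimulated and 2 antigen presentation genes passed, although the interferon median was 3.04; without GFP replicate 3 the counts were 33 and 8.

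Chemokine transcripts were among the largest rises. Of 15 tested cytokine and chemokine genes, 6 rose and none fell. Cxcl10, a lymphocyte attractant, rose from 0.179 ± 0.13 to 20.8 ± 11.6 CPM (log2 fold change 6.86 ± 0.67, adjusted p = 0.00371). Cxcl13, a B cell attractant, stood at 2.92 ± 1.42 CPM with no count in any GFP library, which makes it at least 65.6-fold higher against a floor of 3 counts over the GFP group. Ccl5 and Ccl12 rose with log2 fold changes of 5.13 ± 0.64 and 4.33 ± 0.57. Cxcl10 has an exon that overlaps Art3. In total 9 were higher adjusted over the list alone, 7 with DESeq2 and 4 with limma-voom, and camera placed the list higher (adjusted p = 5.67e-09; 0.184 with an estimated correlation). The list median was 0.95, also with Cxcl13 at its bound, and 0.57 without Caspase3 replicate 1. Of 10 tested T and NK cell markers, 5 rose: Ccl5, Cd3e, Cd8a, Cd8b1 and Ms4a4b. Cd3e, a subunit of the T cell receptor complex, reached 0.709 ± 0.133 CPM against 0.102 ± 0.0328, and Cd8a, the coreceptor of cytotoxic T cells, 1.77 ± 0.545 against 0.222 ± 0.175. Adjusted over the list alone, 7 were higher, with DESeq2 6 and with limma-voom 3 (camera adjusted p = 1.83e-10; 0.184 with an estimated correlation). None of the named chemokine or T cell genes passed without GFP replicate 2 (adjusted p = 0.0502 to 0.168). Of the T and NK list, 1 passed without GFP 3, 2 without GFP 1, 1 without Caspase3 2 and 3 without Caspase3 1. The 1 that passed without GFP 3 or Caspase3 2 was Ccl5, which is also counted among the chemokines. Cd3e missed the threshold when any 1 library was left out (adjusted p = 0.0519 to 0.121), Cd8a also without Caspase3 2 or GFP 3 (0.0626 and 0.0657), Ms4a4b also without Caspase3 2, GFP 1 or GFP 3 (up to 0.094), and Cd8b1 passed without Caspase3 3 only. Without GFP 1, the log2 fold changes of Cxcl10 and Cd8a were 7.57 and 3.77 (2.99 over all libraries for Cd8a).

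Some microglial and complement genes passed. Of 18 homeostatic microglia markers, 8 rose and none fell, with a median log2 fold change of 0.64. Ctss, a lysosomal protease, rose 3.20-fold (log2 fold change 1.68 ± 0.20), Aif1 2.54-fold and Laptm5 2.03-fold. Of 26 tested genes of disease-associated microglia, 8 rose, among them the receptor Trem2 and its adaptor Tyrobp by 2.77-fold and 2.45-fold, the integrin Itgax by 9.03-fold and Cst7, with 12 counts over the GFP libraries (log2 fold change 3.63 ± 0.49, and 4.35 without GFP 1). Complement and Fc receptor genes rose in 11 of 18 cases, among them C3 (22.8-fold), C4b (6.83-fold, 36.1 ± 19.5 to 246.5 ± 86.6 CPM), C1qa (2.75-fold) and Fcgr3 (2.33-fold). Camera placed the lists higher, with adjusted p of 4.51e-13, 4.14e-15 and 2.92e-21, and of 0.188, 0.184 and 0.184 with an estimated correlation. In these lists 13, 18 and 18 members were higher adjusted over the list alone, 11, 14 and 14 with DESeq2 and 7, 9 and 10 with limma-voom. Among 12 tested monocyte, macrophage and neutrophil markers, Lyz2, a lysozyme that microglia also make, rose 2.68-fold (adjusted over the list alone, 7 higher; DESeq2 4, limma-voom 2; camera adjusted p = 1.01e-06; 0.188 with an estimated correlation). Without GFP replicate 2, of these 4 lists only C3 passed. Without GFP replicate 3, 1 homeostatic, 6 disease-associated, 5 complement and no monocyte genes passed; Lyz2 also missed the threshold without Caspase3 3 (adjusted p = 0.0569), and the homeostatic count was 5 without Caspase3 2 and 4 without Caspase3 3 or GFP 1. Aif1 and Laptm5 missed the threshold without GFP 3 (0.0616 and 0.0746), and Laptm5 without GFP 1 (0.0533).

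Reactive astrocyte genes rose in 7 of 28 tested cases. Gfap, the intermediate filament of astrocytes, rose 2.47-fold, from 191.3 ± 40.1 to 473.2 ± 102 CPM (log2 fold change 1.31 ± 0.19, adjusted p = 0.0099). The GTPase Gbp2 rose 7.33-fold, the protease inhibitor Serpina3n 2.58-fold and the cytokine receptor Osmr 2.13-fold. The count adjusted over the list alone was 12 higher, with DESeq2 8 and with limma-voom 6 (camera adjusted p = 6.99e-08; 0.188 with an estimated correlation). None of these 4 genes passed without GFP replicate 2 (adjusted p = 0.0562 to 0.0699), and the list held 4 calls without any 1 Caspase3 library. Among 18 homeostatic astrocyte markers edgeR, DESeq2 and limma-voom called none, and 1 had an unadjusted p under 0.05. Camera placed that list lower without Caspase3 replicate 1 alone (adjusted p = 0.0485; 0.83 over all libraries). The glutamate transporter Slc1a2 was at 6780 ± 1090 and 7439 ± 913 CPM.

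Of 33 tested genes of apoptosis, necroptosis and pyroptosis, 3 rose: the inflammatory caspases Casp1 (3.12-fold) and Casp12 (2.18-fold), and Gsdmd (2.66-fold), which forms pores in pyroptosis. Adjusted over the list alone, 7 were higher, with DESeq2 6 and with limma-voom 2 (camera adjusted p = 3.89e-06; 0.184 with an estimated correlation). The apoptotic regulators Bax and Bbc3 had log2 fold changes of 0.14 and 0.46 and did not pass (adjusted p = 0.834 and 0.694). Mcm6, a replication helicase subunit, was the 1 gene of 18 tested p53 target and cell cycle genes that rose (1.67-fold; camera adjusted p = 0.00893; 0.246 with an estimated correlation). Adjusted over the list alone there was 1 call too, as with DESeq2, and limma-voom made none. Mcm6 missed the threshold when any 1 library was left out (adjusted p = 0.0866 to 0.18), and the list did without Caspase3 2 or GFP 2 (0.0797 and 0.0724). Without GFP replicate 3 or GFP replicate 2, no gene of the cell death list passed, and 1, Casp1, passed without Caspase3 1, Caspase3 3 or GFP 1. Casp12 missed the threshold when any 1 library was left out (adjusted p = 0.0695 to 0.143), and Gsdmd when any other than Caspase3 2 was (0.0816 to 0.167).

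Of 32 immediate early genes, which neurons switch on with activity, none rose, 27 did not pass and 5 fell: Sik1 (1.80-fold, 40.4 ± 2.96 to 22.5 ± 1.51 CPM), Fos (2.06-fold, 80.0 ± 16.9 to 38.9 ± 3.94 CPM), Egr2 (2.04-fold), Dusp5 (1.71-fold) and Nr4a1. Fos and Egr2 encode transcription factors, Sik1 a kinase and Dusp5 a phosphatase. DESeq2 called 12 lower and 1 higher, limma-voom 3 lower, and edgeR with no filter on low counts 18 lower and 1 higher. The median log2 fold change was -0.56. Adjusted over the list alone, 15 were lower and 1, Jun, was higher (log2 fold change 0.66 ± 0.15, adjusted p = 0.0959 over all genes). Camera placed the list lower (adjusted p = 1.15e-09; 0.184 with an estimated correlation). Without GFP replicate 2 none passed (adjusted p of the 4 named first, 0.0562 to 0.211), and without Caspase3 replicate 1 Jun passed as a rise (0.00765). The count of falls was 3 without GFP 3 or GFP 1 and 2 without Caspase3 2. Dusp5 missed the threshold when any 1 library was left out (adjusted p = 0.0718 to 0.211), Egr2 also without Caspase3 2 or GFP 1 (0.0811 and 0.0997), and Nr4a1, of these fits, passed without Caspase3 3 only. Arc passed as a fall without Caspase3 1 (0.0211; 0.161 over all libraries), and without both Caspase3 1 and GFP 3 10 genes fell, with Arc and Npas4 among them (0.00164 and 0.000483), and 1 rose.

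Most neuronal and synaptic lists held few or no calls. Gabrg3, a subunit of the GABA-A receptor, was the 1 of 21 GABA receptor and inhibitory synapse genes that passed, and it fell 1.69-fold (30.4 ± 2.51 to 18.0 ± 1.19 CPM, adjusted p = 0.00992). It missed the threshold without GFP replicate 2 (adjusted p = 0.0684). The list was placed lower by camera (adjusted p = 1.22e-05; 0.246 with an estimated correlation). No gene passed with edgeR among 14 of GABA metabolism and chloride transport (Wnk1, log2 fold change 0.17 ± 0.13), 19 glutamatergic neuron markers (Camk2a, -0.04 ± 0.14), 22 glutamate receptor genes (Gria2, -0.17 ± 0.14), 29 voltage-gated channel genes linked to epilepsy (Scn2a, -0.14 ± 0.14) or 21 presynaptic vesicle genes (Snap25, -0.27 ± 0.16). At an unadjusted p under 0.05 these lists held 3, 3, 3, 10 and 1 genes. DESeq2 called 1, 1, 0, 2 and 1 of them and limma-voom none. Adjusted over the list alone, 1 gene each of the GABA receptor and GABA metabolism lists was lower and none of the others passed. Camera placed the receptor, channel and vesicle lists lower (adjusted p = 0.00215, 5.96e-07 and 0.00116), with medians of -0.16, -0.22 and -0.13, and adjusted p of 0.344, 0.184 and 0.428 with an estimated correlation. For the GABA metabolism and glutamatergic lists its adjusted p was 0.098 and 0.112. The receptor list missed the threshold without Caspase3 1 (adjusted p = 0.163) and the vesicle list without GFP 2 (0.162), while the glutamatergic list was placed lower without GFP 3 (0.00139) or Caspase3 3 (0.0422) and the GABA metabolism list without Caspase3 1 (0.0485). Without Caspase3 1, edgeR called 2 glutamatergic genes higher and 2 channel genes lower, and without Caspase3 2, 1 channel gene lower.

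No gene passed with edgeR in the lists of other cell types and RNA quality. By camera, oligodendrocyte markers were placed higher (median log2 fold change 0.34, adjusted p = 0.000276; 0.440 with an estimated correlation), but not without Caspase3 replicate 1 (adjusted p = 0.0701). Mitochondrially encoded genes were placed lower (median -0.18, adjusted p = 8.1e-05; 0.259 with an estimated correlation; mt-Co1 -0.14 ± 0.20), as were cholesterol synthesis genes (median -0.10, adjusted p = 0.0342; 0.440; Hmgcs1 -0.27 ± 0.13), the latter not without Caspase3 3, GFP 1 or GFP 2 (adjusted p up to 0.38). Mitochondrial transcripts took 7.45% to 9.25% of counts in the Caspase3 libraries and 8.65% to 9.41% in the GFP libraries. Genes of rRNA took 0.0347% of counts in GFP replicate 2 and 0.180% to 0.302% in the other libraries. Whether this bears on the calls was not tested. The camera test over all libraries did not place oligodendrocyte precursor (Pdgfra), endothelial (Flt1), mural and fibroblast (Rgs5), claustrum and endopiriform (Gng2), choroid plexus and ependymal (Kl), hemoglobin (Hbb-bs), heat shock (Hsp90aa1) or seizure-linked neuropeptide and growth factor genes (Rgs4), and adjusted p ranged from 0.072 to 0.917. The choroid plexus list had a median of 0.58 and a mean of -0.02. At an unadjusted p under 0.05, the lists of this paragraph, from oligodendrocyte to neuropeptide in the order given, held 5, 4, 5, 0, 1, 4, 4, 2, 0, 1 and 2 genes, of which DESeq2 called 0, 3, 1, 0, 1, 0, 1, 1, 0, 1 and 0 and limma-voom none. Adjusted over the list alone, 4 mitochondrial genes were lower, 1 choroid plexus gene was higher and none of the others passed. With 1 library left out, camera placed the mural list higher (without Caspase3 2 or GFP 1, adjusted p = 0.000679 and 0.0171), the choroid plexus list higher (Caspase3 1 or 2, 0.0185 and 0.0383), the heat shock list higher (GFP 3, 0.0219), the claustrum list lower (Caspase3 2 or GFP 1, 0.0275 and 0.0224) and the neuropeptide list lower (Caspase3 2 or GFP 1, 0.0144 and 0.00623); edgeR then called up to 2 genes, in the mitochondrial, mural, choroid plexus and heat shock lists. Of 3 tested B and plasma cell markers, too few for a set test, none passed with edgeR, DESeq2 or limma-voom, and 1 did adjusted over the list alone and at an unadjusted p under 0.05 (Pax5, a B cell transcription factor, log2 fold change 2.51 ± 0.68, adjusted p = 0.159 over all genes). Ighm, the highest in counts, had a log2 fold change of 0.33 ± 0.38.

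**Figure D3:**
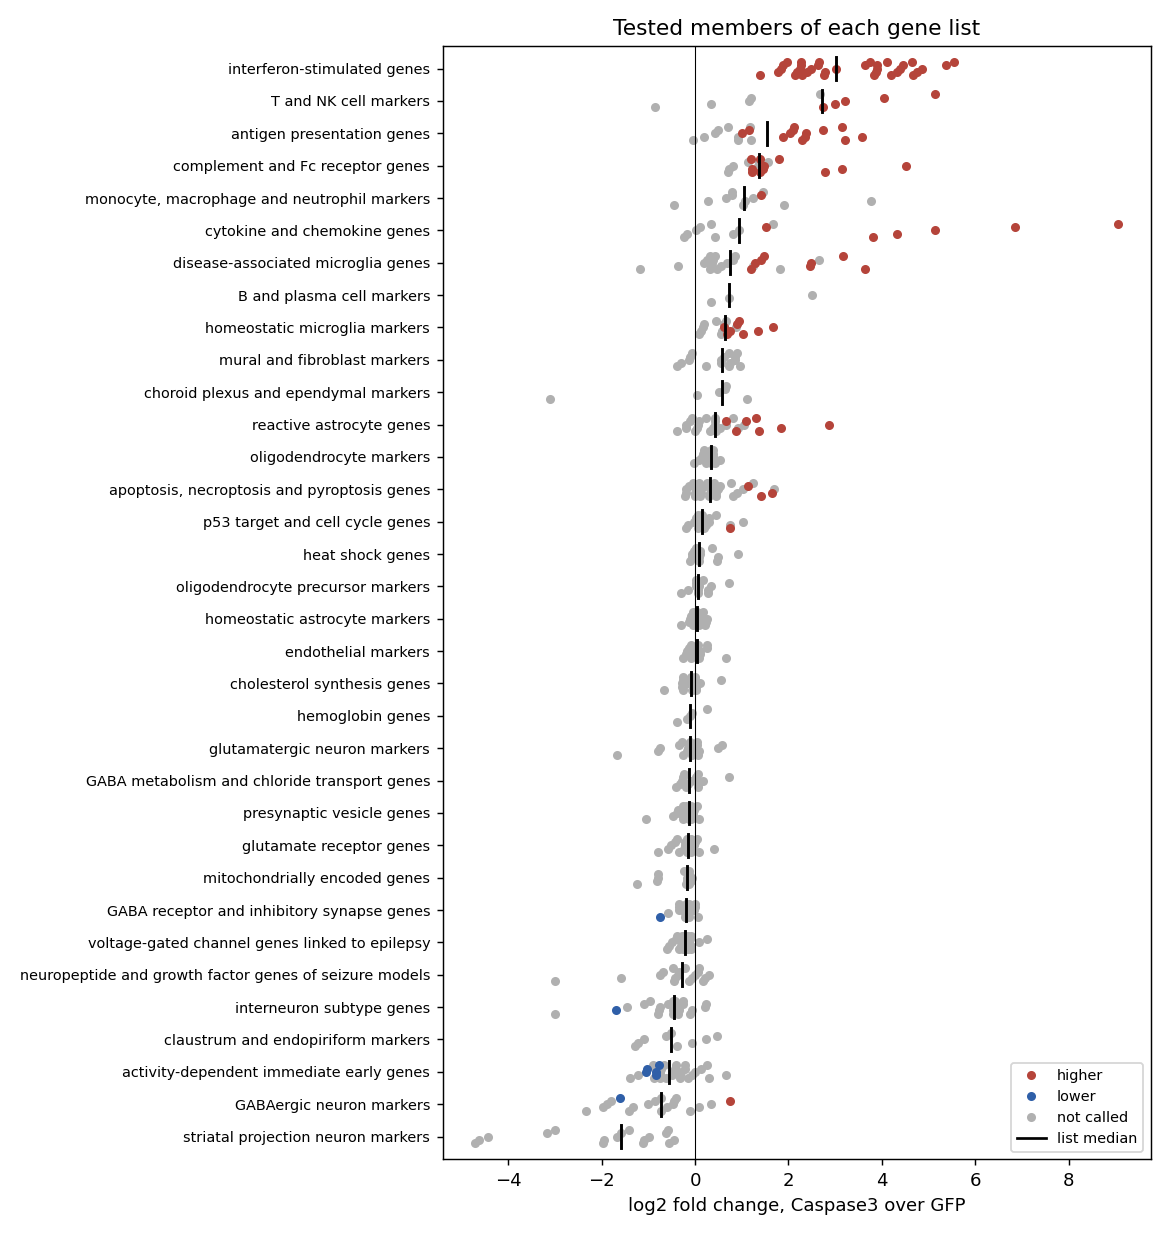
Fitted log2 fold change (Caspase3 over GFP) of each tested member of the 34 gene lists, sorted by list median. Red and blue points are members that rose or fell at an adjusted p under 0.05 in edgeR, grey points did not pass, and black bars are list medians. All 35 interferon-stimulated genes are red, and the striatal list, with a median of -1.58, holds no coloured point.

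Among genes with a mean of at least 1 CPM, predicted genes left out, the 8 largest rises were those of Cxcl13, Cxcl10, Ms4a4c, Ifi206, Oas1g, Ifi213, Mnda and Mx1. Ms4a4c had 1 count over the GFP libraries, in GFP 2, for a count ratio of 141 (95% exact interval 24.9 to 5610), Oas1g had 2 (ratio 74.1, 20.1 to 618) and Mnda had 3 (ratio 60.2, 20.3 to 295). With 1 library left out, their fitted log2 fold changes ran from 6.28 to 8.56, 5.49 to 6.39 and 5.18 to 6.62. The HIN200 genes Ifi206 and Ifi213 had 4 and 6 counts over the GFP libraries, too few for an exact fold. Their fitted log2 fold changes were 6.15 ± 0.78 and 5.78 ± 0.80, that of Ifi206 was 9.71 without GFP 1, which held all 4 counts, and 5.54 without GFP 2, and that of Ifi213 was 5.14 without Caspase3 1 and 6.69 without GFP 3. Like Mnda and Oas1g, both have close copies that could share reads. Hcar2, a receptor below that mean, had 1 GFP count (ratio 67.0, 11.6 to 2690). Its fitted log2 fold change was 5.63, and 7.46 without GFP 2, which held that count. Among the falls, next to Kcns3, Gad2, Fos, Egr2 and Sik1, stood Apold1, an endothelial immediate early gene (2.25-fold, 19.5 ± 1.63 to 8.65 ± 0.368 CPM, adjusted p = 0.00405), Gjd2, a connexin of electrical synapses (2.11-fold), and Rerg, a small GTPase (2.96-fold). Below that mean, Prdm12, a zinc finger protein, fell further (log2 fold change -3.36 ± 0.55, 0.653 ± 0.206 to 0.0573 ± 0.0188 CPM), but missed the threshold when any 1 library was left out (adjusted p = 0.053 to 0.0746), as did Hcar2 without GFP 2 (0.0562). Without GFP replicate 2, Mx1 alone of the 8 largest rises passed, and Gad2 and Apold1 alone of the 8 largest falls. Rerg passed without GFP 1 only, and Gjd2 was also lost without Caspase3 3 or GFP 3 (adjusted p = 0.0598 and 0.06).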

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

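Tests in this part were chosen after the results they concern had been seen. Counts of genes left out of the tests for low counts were summed over each gene list and scaled to library totals times TMM factors. On that scale 5 of 15 lists stood above every GFP library in all 3 Caspase3 libraries. Unscaled, the disease-associated microglia and cholesterol synthesis lists also did, each with 7, 8 and 7 counts against 6, 3 and 1. The cholesterol list had 1 untested member and the counts of both lists were identical, so they may be those of 1 shared gene. Chance gives such a separation in 5% of lists with 3 against 3. For 17 untested T and NK cell markers the sums over the groups were 352 counts in Caspase3 and 61 in GFP. Cd3d had 11, 5 and 6 counts and Prf1, a pore-forming protein of killer cells, 7, 7 and 3 in the Caspase3 libraries, with none in the GFP libraries. Of 14917 untested genes with a count, 114 were counted in all Caspase3 and no GFP libraries and 103 the other way round, so this pattern in a single gene is about as common in either direction. Untested cytokine and chemokine genes had 196 against 41 counts, with Ccl2 at 13, 17 and 2 counts against 1, 1 and 0. Untested monocyte, macrophage and neutrophil markers had 98 against 53, reactive astrocyte genes 83 against 28, and B and plasma cell markers 69 against 31. The last 3 sums rest on few members, and members of the lists did not all go 1 way. Ly6c2 had 18, 20 and 4 counts against 1, 0 and 1, while Pf4 had 11, 7 and 9 against 7, 6 and 13, Napsa 5, 5 and 13 against 4, 9 and 10, Lcn2 3, 4 and 5 against 7, 0 and 5, Il1b 9, 8 and 3 against 7, 4 and 4, and Cd79a 1, 0 and 1 against 3, 2 and 4.

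Gad2 fell in the Caspase3 group, and 16 other GABAergic markers had a median log2 fold change of -0.79. For Gad2, striatal tissue in GFP replicate 3 as the whole cause is argued against, since its log2 fold change without that library was -1.618 (1 SE either side, -1.80 to -1.44; adjusted p = 0.0169), and so is a loss of neurons in general as the whole cause, since Gad2 lay below glutamatergic markers (without Lamp5) by -1.419 without that library, with the nearest libraries of the 2 groups 1.19 apart against a pooled SD of 0.20 between libraries. For the 16 others the median without GFP replicate 3 was -0.69 (95% bootstrap interval over genes, which are not independent replicates, -1.11 to -0.39), but the nearest libraries lay 0.11 apart against a pooled SD of 0.42, so striatal tissue as the whole cause cannot be told apart from other causes for them. They lay below glutamatergic markers by -0.699 (interval -1.39 to -0.39), and by -0.49 (-0.92 to -0.18) without GFP replicate 3, where the nearest libraries lay 0.05 apart against a pooled SD of 0.35, so a loss of neurons in general as the whole cause cannot be told apart for them either. Loss of the targeted neurons, which the design names, stays open as an untested explanation.

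All 35 interferon-stimulated genes of the list rose, of which 6 passed without GFP replicate 2. More microglia with unchanged expression per cell are argued against as the whole cause, since the interferon median exceeded that of homeostatic microglia markers by 2.386 (95% bootstrap interval over genes, 1.74 to 3.30; nearest libraries 1.604 apart, pooled SD 0.35), and 34 of 35 members lay above the largest microglial change of 1.68. Caspase3 replicate 1 as the whole cause is argued against as well, since the median without it was 2.616, 35 of 35 members passed and the nearest libraries lay 1.94 apart against a pooled SD of 0.44. A difference in vector preparation or dose cannot be told apart from the transgene, since 0 libraries received no virus or another vector. A response to the death of the targeted cells therefore may or may not underlie the rise.

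Of 32 immediate early genes 5 fell, with a list median of -0.56, and none of the 32 passed in edgeR without GFP replicate 2. A loss of neurons in general as the whole cause cannot be told apart from other causes, since their median lay below that of glutamatergic markers by -0.464 over all libraries (95% bootstrap interval over genes, -0.73 to -0.21) but by -0.40 with an interval up to 0.02 without GFP replicate 3. Striatal tissue in GFP replicate 3 is argued against as the whole cause, since the median without it was -0.597 (interval -0.89 to -0.20), with the nearest libraries 0.27 apart against a pooled SD of 0.16. The handling of animals before dissection, which the labels do not describe, and the treatment itself stay open as untested explanations.

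For the count of changed genes, the 6 libraries allow 10 splits into 3 and 3, and 1 of these, the real one, gave 274 genes. The highest of the others gave 1 gene, and 10 splits are too few for a share under 0.05.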

How the results depend on the processing

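The fit without both Caspase3 replicate 1 and GFP replicate 3 was chosen after seeing the data. Gad2 kept its call in all 21 alternatives (log2 fold change -1.69 to -1.45, adjusted p up to 0.0494). Of these, the settings of at least 1.5-fold and of an adjusted p under 0.1 reused the fit to all libraries. No named gene could lose its call in them. None of the 274 changed genes turned sign in any alternative. Their groups did not overlap, so leaving out libraries could hardly have turned a sign. Of 50 named genes called, 9 were called in every alternative, 41 were lost without GFP replicate 2 and 14 without GFP replicate 3. Against 274 genes (255 higher, 19 lower), DESeq2's Wald test called 495 (397 and 98), no filter on low counts 913 (663 and 250), limma on log2(FPKM + 1) 170 (160 and 10), an adjusted p under 0.1 gave 40 lower, and leaving out both named libraries gave 77 lower; the cause was not tested. The all-gene median moved by at most 0.06 under other scalings. Leaving out 1 library gave 17 to 285 changed genes, 15 to 252 higher and 2 to 33 lower. The lowest counts came without GFP replicate 2, where 83 genes had an adjusted p under 0.06 and 1321 an unadjusted p under 0.05. Same-numbered libraries deviated with correlations of 0.065, 0.178 and 0.027, and differently numbered ones with -0.142 to 0.079. Caspase3 2 and Caspase3 3 correlated best with their own number, and Caspase3 1 with GFP 3. The correlations are small, so whether the numbers pair the libraries stays open. With the replicate block 421 genes were called, 43 of them lower, 266 shared with the 274. Camera placed 22 lists, 0 with an estimated correlation and 9 by fry, and 19 to 25 with 1 library left out. The first component held 45.3% of the variance over all tested genes. Sign changes were limited to genes and lists not called over all libraries. Over fits with 1 library left out, log2 fold changes ran from -0.881 to 0.0405 for Sst, -0.099 to 0.0474 for Camk2a, -0.028 to 0.0705 for Pdgfra, -0.11 to 0.842 for Ighm, -0.267 to 0.2 for Gng2, -0.172 to 0.0261 for Hbb-bs and -0.164 to 0.0101 for Hsp90aa1. List medians ran from -0.0879 to 0.124 for homeostatic astrocyte markers (placed lower without Caspase3 1, adjusted p = 0.0485), 0.00812 to 0.181 for oligodendrocyte precursor markers, whose test alone changed direction, -0.0598 to 0.074 for endothelial markers and -0.309 to 0.0287 for hemoglobin genes. Without both named libraries Camk2a was 0.0148, Pdgfra -0.0482, Ighm -0.281, Gng2 0.00729, Hsp90aa1 0.0315, the homeostatic astrocyte median -0.0798 and the neuropeptide median 0.033. Camk2a was 0.0209 with library totals alone. Pdgfra was -0.000777 with DESeq2 size factors, -0.00185 with DESeq2, -0.000211 with log2(FPKM + 0.1) and -0.000314 with log2(FPKM + 1). With 3 libraries a group, depth and spread left most 1.5-fold changes undetected in simulated counts, where edgeR recovered 20.9%.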

Other observations

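Of the 274 changed genes, 159 that rose and 11 that fell lay outside the gene lists. The families counted here were chosen from the genes that rose, after their values were seen, so their counts are no test of enrichment. All 7 tested immunity-related GTPases rose, as did 8 of 9 guanylate-binding proteins, 9 of 10 HIN200 genes of chromosome 1, 7 of 8 oligoadenylate synthetase genes and 5 of 6 Schlafen genes. The counts of these families were 2, 0, 2, 2 and 1 without GFP replicate 2, and without Caspase3 replicate 2 that of the Schlafen genes was 3. Some of these belong to the interferon list too, and reads of near-identical copies were not separated. Of 46 tripartite motif genes 8 rose, of 11 Toll-like receptor genes 4, of 12 PARP genes 4, of 8 MS4A genes 3, of 11 cathepsin genes 2, of 6 GIMAP GTPases 1 and of 274 solute carrier genes 1. These counts were 1, 1, 0, 0, 0, 0 and 0 without GFP replicate 2. The tripartite motif count was also 5 without Caspase3 1 or 2 and 3 without GFP 3, and the Toll-like receptor count 2 without GFP 3. The MS4A count was 1 without Caspase3 2, the cathepsin count 4 without Caspase3 1 and 1 without GFP 3, and the solute carrier count 5 without Caspase3 1, 2 without Caspase3 3 or GFP 1 and 0 without GFP 3.

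The single genes of this paragraph were chosen after their values were seen, and do not measure how widely genes rose. Ptprc, the common leukocyte antigen, rose from 7.51 ± 2.17 to 21.5 ± 3.24 CPM (SD, n = 3; edgeR adjusted p = 0.0079), and Spi1 and Irf8, transcription factors of microglia and macrophages, had log2 fold changes of 1.48 ± 0.25 and 1.42 ± 0.20. The cytosolic RNA sensor Ddx58 had 2.48 ± 0.33, the endosomal sensor Tlr7 1.29 ± 0.17 and the immune checkpoint ligand Cd274 2.62 ± 0.35. Grn, Hexa and Lgmn had 0.72 ± 0.14, 0.62 ± 0.12 and 0.67 ± 0.13. Among the falls outside the lists, the kinase Camk4 went from 376.7 ± 48.3 to 217.8 ± 39.5 CPM and Spock3 from 175.5 ± 12.5 to 120.1 ± 6.68 CPM (adjusted p = 0.0414 and 0.0239). None of these 11 genes passed without GFP replicate 2 (adjusted p = 0.0562 to 0.194). Spi1, Grn, Hexa, Lgmn, Camk4 and Spock3 were also lost without GFP 1 or GFP 3, the last 4 without Caspase3 3, Hexa without Caspase3 1 and Spi1 without Caspase3 2. Cd4 did not pass, at 0.913 ± 0.478 against 1.67 ± 2.14 CPM, with 4.13 CPM in GFP replicate 3, and its log2 fold change was -0.86 over all libraries and 1.06 without that library. Transcripts of interferons themselves were nearly uncounted. Over all 6 libraries Ifnb1, Ifna1 and Ifnk had 1 count each.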
